A study of Drosophila melanogaster with 9 samples.

How the data were processed

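RNA-seq was done on 9 libraries of 3 groups of Drosophila brain tumours: sorted primary tumour cells, masses of the first transplantation (T0) and masses of the fourth (T3). Per the labels, polyadenylated RNA was made into libraries with 13 PCR cycles and sequenced as single reads of 75 nt on an Illumina NextSeq. The submitters' processing notes name HISAT2 2.1.0, bedtools 2.25.0, HTSeq and edgeR (versions of both not given) and the genome build dm6. The annotation release and the strand setting of the counting are not given in the sources used here.

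The authors deposited 3 tables, 1 per pairwise comparison, with the same 16727 gene symbols and the same 9 columns of raw read counts per gene. Each deposited table also holds the authors' fold change as a ratio, the log2 fold change as the authors computed it, and the authors' unadjusted and adjusted p-values for its comparison. The deposited counts were used for all tests, and the deposited fold changes and p-values were used to count the authors' calls and, for named genes of T3 against T0, printed as the authors' values. Another 9 per-sample value columns per table, of normalised values and group means, were not used. No count was changed, and 0 table lines lacked a gene name.

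Depth was 7932772 to 14093032 counts per library. A count of 0 over the libraries of a group was treated as a floor of 3 counts over that group, and folds against such a group are lower bounds. For groups with 1 to 3 counts, the ratio carries an exact (Clopper-Pearson) 95% counting interval. PCR reads without molecular identifiers are not independent molecules, so these intervals and floors cover counting error only. The counts of the replicate pairs within groups differed by a chi-square per degree of freedom of 14.5 to 72.5, which is more than repeated sampling of 1 library gives. The p-values measure the spread between these libraries, each a pool of animals.

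Samples were grouped as the labels group them, with 3 libraries each. Genes were tested in R 4.3.3 with edgeR 4.0.16: TMM factors, filterByExpr with a minimum count of 10, 1 fit over all 9 libraries with a mean per group, and the quasi-likelihood test. This left 9082 genes tested. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and all p-values are two-sided. SE of a log2 fold change is its size divided by the square root of the F statistic. CPM are counts divided by TMM-scaled library sizes in 1e6 counts, given as mean ± SD over 3 libraries.

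The comparisons, tests, alternatives, rule for named genes and 28 gene lists were chosen before the data were examined. The lists cover transgenes and marker, neuroblast identity, the Notch pathway, early temporal genes, late temporal and ecdysone response genes, asymmetric division, neuronal differentiation, glia, cell cycle, growth, glycolysis, oxidative phosphorylation, JNK and invasion, JAK/STAT and receptor tyrosine kinase output. They also cover antimicrobial response, hemocytes, basement membrane, adult fat body, muscle, gut, ovary, trachea, heat shock and dissociation, DNA damage response, Hox genes, optic lobe, and sex and dosage compensation. Lists were tested with camera (limma 3.58.1) on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, beside a correlation estimated per list. Adjustment was over the 27 lists with at least 3 members tested. No list call under the preset correlation held with an estimated correlation. With an estimated correlation, camera also takes its degrees of freedom from the number of libraries, not of genes. The settings therefore differ in more than the correlation. Members that also stand in another list numbered 4 for cell cycle, 3 for asymmetric division, 0 or 1 for the others. List symbols and deposited symbols were matched through the synonyms of the reference annotation, which 48 of 420 members needed. Positions come from the Ensembl annotation of the dm6 assembly.

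Most genes named in the text follow 3 rules. The first takes, per comparison, the 10 largest positive and 10 largest negative log2 fold changes among called genes with a mean of at least 5 CPM and groups that do not overlap. Genes with a bare CG or CR number may be given as a count. The next takes, per list and comparison, up to 4 called members with the smallest adjusted p and up to 2 uncalled members with the smallest p. The last always takes dpn, E(spl)mgamma-HLH, w, chinmo, Imp, Syp, Eip93F, ase, mira, pros, elav, repo, Hml, Ldh, Mmp1 and upd3. Named beside these are members that moved against their list, members adjusted over the list alone, genes that may share reads, the gene with most counts, and genes that the authors or an alternative called between T3 and T0.

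Alternatives were other scaling factors (RLE, upper quartile), no filter, a filter of CPM of at least 1 in 3 libraries, DESeq2 1.42.0, limma-voom, a fit on the 6 libraries of the 2 groups compared, the replicate number as a block, a test against a 1.5-fold change, and leaving out each library. Only T0 replicate 3 carries the number 3, so the fit with the replicate block in effect leaves that library out. A likelihood ratio test and a model with 1 surrogate variable (sva 3.50.0) were added after the data were seen. The pipeline was tested on simulated data with 200 changed genes of 9082. For T0 against primary it recovered 14%, 52%, 88% and 94% of genes changed 1.5-, 2-, 4- and 8-fold, with 11 false calls. For T3 against T0 it recovered 20%, 74%, 92% and 92%, with 5 false calls. The simulated counts were drawn independently around each gene's mean over all 9 libraries, with no structure among libraries. These shares therefore need not hold for the real libraries.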

Results

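RNA-seq measured polyadenylated transcripts in brain tumours of Drosophila melanogaster at 3 stages. The tumours arose from larval brain clones that overexpressed deadpan (dpn) and E(spl)mγ, genes of the HES family whose products repress transcription in neural stem cells (neuroblasts). The primary group held GFP-positive clone cells sorted by flow cytometry after collagenase dissociation, from 150 larval brains per replicate, 4 days after clone induction. The T0 group held the masses that grew when tumours were first transplanted into adult flies, and the T3 group those of the fourth round of transplantation. T0 and T3 masses came from 25 adult w1118 hosts per replicate after 8 to 10 days and were not sorted. Each group had 3 libraries, with 1 library per replicate.

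Total counts over the 16727 gene symbols were 14093032, 13035997 and 11040373 in primary replicates 1, 2 and 4, 9482014, 10659802 and 12988767 in T0 replicates 2, 3 and 4, and 7932772, 11152658 and 12830347 in T3 replicates 2, 4 and 1. The gene with most counts in every library was the noncoding RNA gene CR43283, with 2.11% to 4.06% of the counts. Across genes, which are not independent replicates, Pearson correlations of log2 CPM (counts per 1e6 counts of a library) were 0.971 to 0.987 within groups. They were 0.829 to 0.892 between primary and T0, 0.828 to 0.879 between primary and T3, and 0.969 to 0.988 between T0 and T3. The first principal component held 76.4% of the variance and parted primary from both transplanted groups. On the second component, with 6.79%, T0 replicate 2 lay at 33.3 against -28.5 and -15.8 for T0 replicates 3 and 4. The T3 libraries were also spread along it, at 8.85, -21.1 and 20.2 for replicates 2, 4 and 1.

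**Figure D1:**
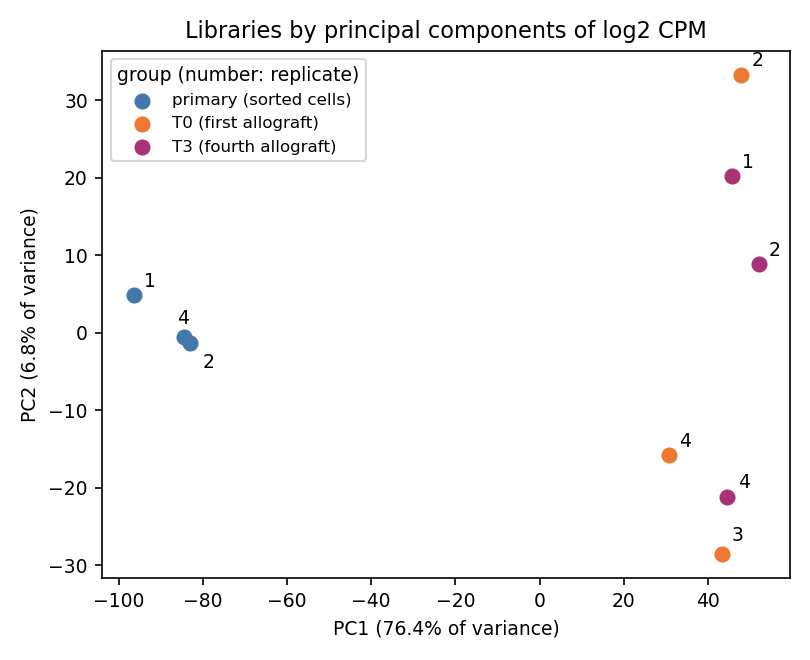
Each point is 1 of the 9 libraries, placed by its scores on the first and second principal components of log2 CPM, with the share of variance on each axis. The first component, with 76.4% of the variance, separates the 3 primary libraries from the 6 T0 and T3 libraries, and T0 replicate 2 lies at 33.3 on the second.

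The comparison of T0 with primary asks how tumours grown for the first time in adult hosts differ from the tumour cells of the larval brain. In T0 masses, 20 of 25 neuronal genes, 6 of 6 Hox genes and 9 of 15 Notch pathway genes fell, while 2 neuronal genes rose. Among genes that rose were 13 of 16 of the DNA damage response, 9 of 16 antimicrobial, 8 of 11 blood cell and 7 of 9 basement membrane genes. These 7 lists passed with a preset correlation, and none did with an estimated one (adjusted p = 0.163 to adjusted p = 0.656 with an estimated correlation). The synaptic vesicle gene nSyb (chromosome arm 3L, 1630348 to 1637752, dm6) fell from 99.4 ± 17.5 to 3.96 ± 0.325 CPM (mean ± SD, n = 3 libraries per group). Its log2 fold change was -4.65 ± 0.24 (SE), with an adjusted p = 1.28e-07. The blood cell gene Hml (3L, 13846054 to 13860001) rose from 2.35 ± 1.17 to 29.1 ± 16.3 CPM (log2 fold change 3.64 ± 0.49, adjusted p = 1.07e-04). The RNA-binding protein gene lin-28 (3L, 5654681 to 5657384), active in early development, rose from 4.52 ± 1.64 to 62.3 ± 32.7 CPM (log2 fold change 3.79 ± 0.42, adjusted p = 2.85e-05).

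In all, 4144 of the 9082 genes tested passed the threshold, 2037 higher and 2107 lower in T0. Of these, 963 were higher and 1057 lower by at least 2-fold, and 218 and 527 by at least 8-fold. The 3 libraries of each group lay fully apart for 54.8% of the genes tested, where chance gives 10%. The authors' table calls 4164 genes, 4021 of them also called here, none with the opposite sign. A test against a 1.5-fold change called 1898 genes. Sorting, dissociation, host and growth time all differ between these groups, so the comparison covers all of them at once.

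Both overexpressed genes were present at lower levels in T0. dpn (2R, 8228971 to 8232330) fell from 639 ± 54.8 to 253 ± 73.6 CPM (log2 fold change -1.34 ± 0.20), and E(spl)mgamma-HLH (3R, 25999851 to 26000761) from 503 ± 27.2 to 181 ± 56.7 CPM (-1.48 ± 0.19). The counts do not part transgene from endogenous transcripts. The eye colour gene w (X, 2790599 to 2796466), carried by many fly transgenes and mutated in the hosts, was at 429.5 ± 27.0 CPM in primary and 478 ± 63.5 CPM in T0 and was not called. As a list, these 3 genes did not pass (adjusted p = 0.238), and 0 rose and 2 fell of 3 tested, also adjusted over the list alone. Of the Notch pathway list, 0 rose and 9 fell of 15 tested, also adjusted over the list alone, with a median log2 fold change of -1.20 (camera, adjusted p = 0.00122, and adjusted p = 0.163 with an estimated correlation). Among them were the Notch targets Hey (-3.74 ± 0.38) and E(spl)m7-HLH (-3.13 ± 0.32) and the ligand gene Ser (-3.49 ± 0.40). Su(H), the pathway's DNA-binding factor, was at 47.4 ± 3.76 and 38.4 ± 2.15 CPM and was not called.

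Of the neuroblast identity list, 5 rose and 5 fell of 15 tested, also adjusted over the list alone, and the list did not pass (median -0.04, adjusted p = 0.933). The proneural gene ase fell from 195 ± 24.3 to 39.3 ± 7.47 CPM (log2 fold change -2.31 ± 0.22) and l(1)sc fell too (-2.12 ± 0.48), while grh, a late neuroblast factor, rose (0.78 ± 0.17). mira, which encodes an adaptor that carries fate determinants, rose from 1834 ± 78.0 to 2491 ± 262 CPM (0.44 ± 0.15, adjusted p = 0.0304). Its adjusted p was 0.0709 without primary replicate 2, 0.107 without primary replicate 4 and 0.137 without T0 replicate 3. It was 0.0724 in a fit on the 6 libraries of these groups and 0.146 with the replicate number as a block. In the asymmetric division list 2 rose and 3 fell of 15 tested, also adjusted over the list alone, and the list did not pass (median 0.03, mean -0.20, test direction down, adjusted p = 0.851). Its member pros (3R, 11328480 to 11407627), which drives daughter cells to differentiate, fell from 962 ± 311 to 118 ± 26.1 CPM (log2 fold change -3.02 ± 0.25, adjusted p = 2.89e-06). l(2)gl, a cell polarity gene of the same list, rose (0.81 ± 0.15).

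Of the early temporal list, genes of young neuroblasts, 3 rose and 2 fell of 7 tested (4 and 2 adjusted over the list alone), and the list did not pass (median 0.77, adjusted p = 0.671). Beside lin-28, chinmo (2L, 1651258 to 1704682) rose from 282 ± 33.4 to 555 ± 116 CPM (0.98 ± 0.17), as did svp (1.11 ± 0.21). Imp (X, 10787869 to 10824277), an RNA-binding protein gene of early neuroblasts, was at 384 ± 89.5 and 655 ± 248 CPM (log2 fold change 0.77 ± 0.33) and was not called (adjusted p = 0.0741). It passed without T0 replicate 2 (0.0345) or T3 replicate 2 (0.0294), and in a fit on the 6 libraries of the 2 groups (0.78, adjusted p = 0.0337). Of the late temporal and ecdysone response list, 2 rose and 4 fell of 12 tested, also adjusted over the list alone, and the list did not pass (median -0.46, adjusted p = 0.671). The ecdysone receptor gene EcR rose (1.08 ± 0.16), as did ftz-f1 (1.14 ± 0.15). Syp (3R, 20756729 to 20810726), a counterpart of Imp in late neuroblasts, was at 2359 ± 1001 and 1309 ± 609 CPM, and Eip93F at 93.4 ± 55.5 and 52.2 ± 24.8 CPM. Neither was called (adjusted p = 0.103 and 0.101). Syp passed without primary replicate 4 (0.0417) or T0 replicate 4 (0.0435), and Eip93F passed without the same libraries (0.0284 and 0.0294).

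Of the neuronal list, 2 rose and 20 fell of 25 tested (2 and 21 adjusted over the list alone), with a median log2 fold change of -3.43 (camera, adjusted p = 4.84e-08, and adjusted p = 0.519 with an estimated correlation). Examples were the synaptic genes Rab3 (-4.15 ± 0.21) and Syt1 (-5.35 ± 0.33), and elav (X, 509235 to 523226), which encodes a neuronal RNA-binding protein, from 649 ± 183 to 168 ± 31.0 CPM (-1.95 ± 0.23). The members that rose were cac and unc-13, which act in synaptic release. Of the glial list, 2 rose and 5 fell of 10 tested, also adjusted over the list alone, and the list did not pass (median -1.23, adjusted p = 0.385). The glial regulator repo fell (-2.49 ± 0.49) and the glutamate transporter gene Eaat1 rose (1.40 ± 0.23). Of the Hox list, 0 rose and 6 fell of 6 tested, also adjusted over the list alone, with a median of -5.95 (camera, adjusted p = 3.61e-05, and adjusted p = 0.213 with an estimated correlation). abd-A (3R, 16807214 to 16830049) had 593 counts in the 3 primary libraries and 1 in T0, a 538-fold difference (95% exact counting interval 96.2 to 21286). Scr had 168 counts in primary and 2 in T0, a 76.2-fold difference (counting interval 20.8 to 634). The log2 fold change of abd-A was -8.56 ± 0.89, and it was -7.68 without primary replicate 1 and -10.42 without T0 replicate 4. Of the optic lobe list, 1 rose and 7 fell of 14 tested, also adjusted over the list alone, with a median of -0.90 (camera, adjusted p = 0.0257, and adjusted p = 0.620 with an estimated correlation). Examples were the transcription factor genes ey (-3.93 ± 0.29), dac (-3.38 ± 0.41) and Vsx1 (-2.35 ± 0.36). The list's adjusted p was 0.0716 without primary replicate 1 and 0.0696 without T0 replicate 2.

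Of the cell cycle list, 0 rose and 7 fell of 25 tested (0 and 4 adjusted over the list alone), and the list did not pass (median -0.21, adjusted p = 0.0614). It passed without primary replicate 4 (0.0107), T0 replicate 3 (0.0149) or T0 replicate 4 (0.0432). The mitotic kinase gene Cdk1 fell (-1.04 ± 0.17), as did the replication inhibitor gene geminin (-0.87 ± 0.17). Of the growth and ribosome biogenesis list, 1 rose and 11 fell of 16 tested, also adjusted over the list alone, with a median of -0.53 (camera, adjusted p = 0.00564, and adjusted p = 0.620 with an estimated correlation). The nucleolar gene nop5 fell (-1.04 ± 0.17), and the member that rose was the growth regulator Myc (0.90). Of the oxidative phosphorylation list, 0 rose and 18 fell of 26 tested, also adjusted over the list alone, with a median of -0.50 (camera, adjusted p = 0.00145, and adjusted p = 0.656 with an estimated correlation). The cytochrome c gene Cyt-c-p was among them (-1.15 ± 0.19). Of the glycolysis list, 1 rose and 5 fell of 14 tested, also adjusted over the list alone, and the list did not pass (median -0.32, adjusted p = 0.471). The lactate dehydrogenase gene Ldh (ImpL3 in the deposited table) fell from 134 ± 39.0 to 15.8 ± 8.47 CPM (-3.07 ± 0.65). Of the DNA damage response list, 13 rose and 0 fell of 16 tested, also adjusted over the list alone, with a median of 0.80 (camera, adjusted p = 0.00145, and adjusted p = 0.163 with an estimated correlation). Among these were the genes of the MRN complex, which binds DNA ends: rad50 (1.69 ± 0.15), nbs (1.09 ± 0.15) and mre11 (1.04 ± 0.16).

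Genes of other cell types moved with the groups. Of the hemocyte (blood cell) list, 8 rose and 0 fell of 11 tested, also adjusted over the list alone, with a median of 3.56 (camera, adjusted p = 0.00440, and adjusted p = 0.620 with an estimated correlation), and 5 of the 11 were at or above 1 CPM in primary. Of the basement membrane list, 7 rose and 0 fell of 9 tested, also adjusted over the list alone, with a median of 2.12 (camera, adjusted p = 0.00564, and adjusted p = 0.620 with an estimated correlation). The collagen gene Col4a1 (Cg25C in the deposited table) rose from 8.23 ± 2.95 to 86.6 ± 74.1 CPM (3.40 ± 0.53), with 169.9, 62.1 and 27.9 CPM in T0 replicates 2, 3 and 4. Without T0 replicate 2 its log2 fold change was 2.46. Of the antimicrobial list, 9 rose and 0 fell of 16 tested (10 and 0 adjusted over the list alone), with a median of 3.18 (camera, adjusted p = 0.00564, and adjusted p = 0.656 with an estimated correlation), and 2 of the 16 were at or above 1 CPM in primary. The antimicrobial peptide gene DptA (Dpt in the deposited table, 2R, 18865765 to 18866260) had 157 counts in T0 and 0 in primary, at least 57.7-fold higher against a floor of 3 counts over the group. Its fitted log2 fold change was 8.94 ± 2.18, and 7.97 without T0 replicate 2, sizes that are not exact with 0 counts in primary. By limma-voom DptA was not called (6.11, adjusted p = 0.0652). Of the adult fat body list, 8 rose and 1 fell of 11 tested, also adjusted over the list alone, with a median of 2.45 (camera, adjusted p = 0.0175, and adjusted p = 0.519 with an estimated correlation). The yolk protein gene Yp3 (3.49 ± 0.58) and the lipoprotein gene apolpp (2.45 ± 0.45) rose. The reads of DptA and DptB, of AttA and AttB, of CecA1 and CecA2, and of the Hsp70 copies may map to more than 1 copy, so values for single copies are uncertain.

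Of the heat shock and dissociation list, 2 rose and 8 fell of 17 tested, also adjusted over the list alone, with a median of -1.04 (camera, adjusted p = 0.0335, and adjusted p = 0.656 with an estimated correlation). The immediate-early genes sr (-6.55 ± 0.39) and Hr38 (-3.06 ± 0.40) fell, and kay, the Fos gene, rose (0.92 ± 0.17). Cell dissociation and sorting can raise genes of this list, and only primary cells were sorted. Handling and tumour stage therefore cannot be told apart here. The list's adjusted p was 0.105 without primary replicate 1, 0.0581 without primary replicate 2, 0.0685 without T0 replicate 3 and 0.122 without T0 replicate 4. Of the JNK and invasion list, 4 rose and 1 fell of 11 tested (4 and 2 adjusted over the list alone), and the list did not pass (median 0.09, adjusted p = 0.671). The matrix protease gene Mmp2 rose (1.30 ± 0.16) and the death gene rpr fell (-3.98 ± 0.47). Mmp1 was at 6.69 ± 2.11 and 4.25 ± 0.720 CPM and was not called, and the cytokine gene upd3 had 10 counts over the 9 libraries and was not tested. Of the JAK/STAT list, 3 rose and 1 fell of 9 tested, also adjusted over the list alone, and the list did not pass (median 0.12, adjusted p = 0.359). Of the receptor tyrosine kinase list, 8 rose and 4 fell of 14 tested (8 and 5 adjusted over the list alone), and the list did not pass (median 0.86, mean -0.17, test direction up, adjusted p = 0.294). The ligand genes vn (2.73 ± 0.36) and spi (1.26 ± 0.17) and the receptor gene Egfr (1.11 ± 0.17) rose.

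The other lists did not pass in T0 against primary. In the muscle list 1 rose and 1 fell of 7 tested, also adjusted over the list alone (median 0.46, adjusted p = 0.671). In the ovary and germline list 3 rose and 1 fell of 12 tested, also adjusted over the list alone (median 0.76, adjusted p = 0.540). In the trachea list 2 rose and 2 fell of 6 tested, also adjusted over the list alone (median 0.98, test direction down, adjusted p = 0.966). In the sex and dosage compensation list 2 rose and 0 fell of 6 tested, also adjusted over the list alone (median 0.23, adjusted p = 0.336). The gut list had 2 members tested, and 1 of them, the protease gene Jon65Aiii, rose, also when adjusted over the list alone. Jon65Aiii and the egg yolk receptor gene yl were highest in T0 replicate 2, at 8.27 and 27.7 CPM, against 1.37 and 3.39 CPM in T0 replicate 3. The log2 fold change of Jon65Aiii was 5.70 ± 1.42, 3.98 without T0 replicate 2 and 8.23 without primary replicate 1. That of yl was 5.03, 3.00 without T0 replicate 2 (adjusted p = 0.0729), 4.58 without primary replicate 2 (adjusted p = 0.0507) and 5.87 without primary replicate 1. By limma-voom yl was not called (4.07, adjusted p = 0.0616). Among the 10 largest increases at a mean of at least 5 CPM, lcs was at least 274-fold higher and CG16826 at least 1103-fold higher, both with 0 counts in primary. Among the 10 largest decreases, the neuropeptide gene Nplp1 fell (-7.72 ± 0.30), as did oc, which patterns the head (-7.49 ± 0.33), and igl (-7.37 ± 0.33). CR45601 (5.49) lies antisense to the yolk protein gene Yp1, and the strand setting of the counts is not given in the sources used here, so its reads may be those of Yp1.

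**Figure D2:**
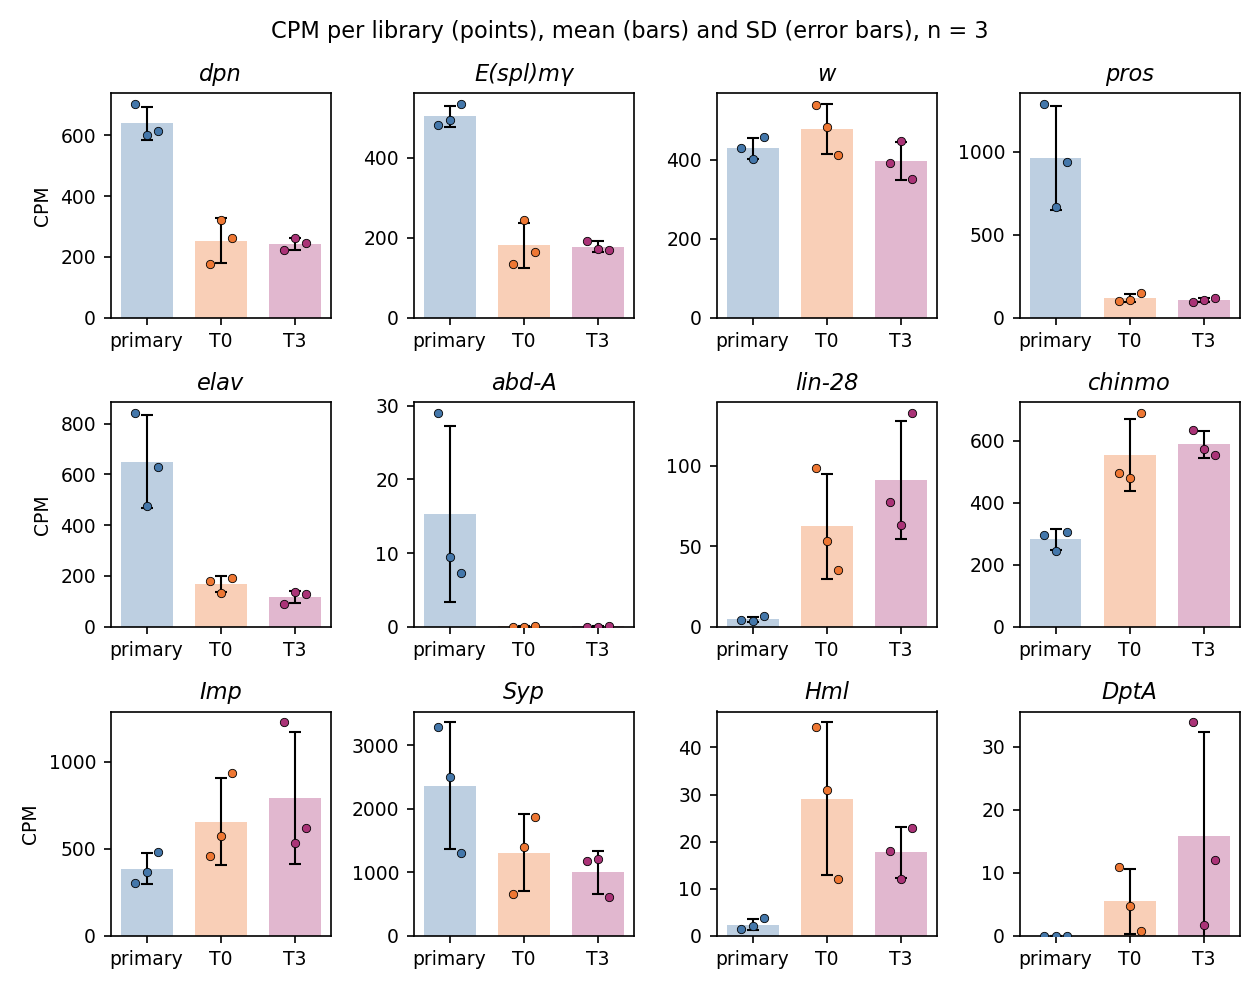
CPM of 12 genes in the primary, T0 and T3 groups, with bars for the mean, error bars for the SD and points for the 3 libraries of each group. dpn falls from 639 CPM in primary to 253 CPM in T0 and 243 CPM in T3, while lin-28 rises from 4.52 to 62.3 and 91.0 CPM.

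**Figure D3:**
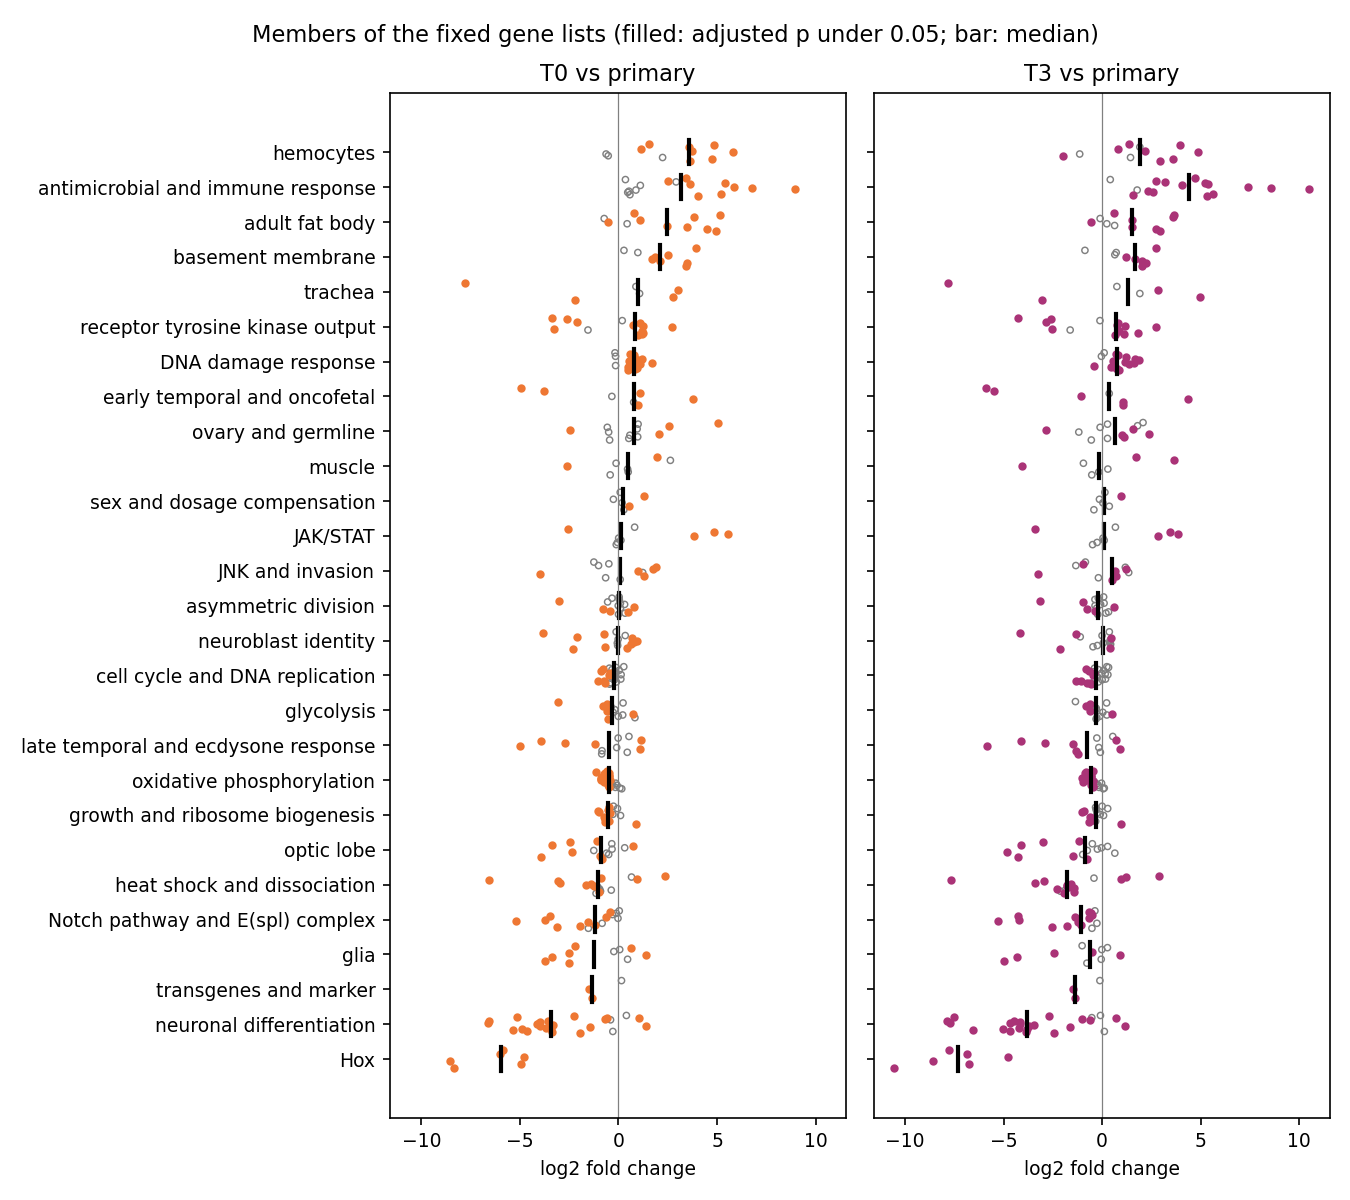
Log2 fold changes in T0 and in T3 against primary for each tested member of the 27 gene lists with at least 3 members tested, 1 point per gene, filled where the adjusted p is under 0.05, with a bar at the list's median. In T0, the neuronal list has a median of -3.43 and the Hox list of -5.95, while the hemocyte list has a median of 3.56.

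The comparison of T3 with primary asks the same of tumours that had passed through 4 rounds of transplantation. In T3 masses, 20 of 25 neuronal genes and 6 of 6 Hox genes fell and 14 of 16 antimicrobial genes rose, while 2 neuronal genes rose. These 3 lists did not pass with an estimated correlation (adjusted p = 0.588, adjusted p = 0.220 and adjusted p = 0.611 with an estimated correlation). pros fell from 962 ± 311 to 107 ± 11.3 CPM (log2 fold change -3.17 ± 0.25, adjusted p = 1.60e-06, n = 3 libraries per group). lin-28 rose from 4.52 ± 1.64 to 91.0 ± 36.7 CPM (log2 fold change 4.35 ± 0.43, adjusted p = 9.46e-06). nSyb fell to 3.85 ± 1.40 CPM (log2 fold change -4.66 ± 0.24), and Hml rose to 17.7 ± 5.41 CPM (2.93 ± 0.48).

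Of the 9082 genes tested, 4284 passed, 2097 higher and 2187 lower in T3. Of these, 991 and 1126 changed by at least 2-fold, and 184 and 580 by at least 8-fold. The libraries of the groups lay apart for 57.9% of genes, where chance gives 10%. The authors' table calls 4316 genes, 4146 of them also called here, none with the opposite sign. A test against a 1.5-fold change called 2006 genes. As in T0, sorting, host and growth time differ between the groups.

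dpn was at 243 ± 19.7 CPM (-1.39 ± 0.20) and E(spl)mgamma-HLH at 178 ± 12.8 CPM (-1.50 ± 0.19), and both fell. w was at 397 ± 48.4 CPM and was not called. With these 3 genes 0 rose and 2 fell of 3 tested, also adjusted over the list alone, and their list did not pass (median -1.39, adjusted p = 0.127). Of the Notch list, 0 rose and 12 fell of 15 tested (0 and 13 adjusted over the list alone), with a median of -1.09 (camera, adjusted p = 1.15e-04, and adjusted p = 0.0901 with an estimated correlation). Hey (-4.19 ± 0.39) and Ser (-4.24 ± 0.42) were among them. Of the neuroblast list, 2 rose and 3 fell of 15 tested (0 and 3 adjusted over the list alone), and the list did not pass (median 0.06, test direction down, adjusted p = 0.899). ase fell (-2.12 ± 0.21), as did the phosphatase gene stg, which triggers mitosis (-1.30 ± 0.27). mira rose (0.40 ± 0.15, adjusted p = 0.0458), but its adjusted p was 0.0596, 0.0921 and 0.139 without primary replicates 1, 2 and 4, 0.0599 without T0 replicate 3, and 0.0983, 0.0963 and 0.105 without T3 replicates 2, 4 and 1. It was 0.0543 with RLE factors and 0.0630 with the replicate block. In the asymmetric division list 1 rose and 4 fell of 15 tested, also adjusted over the list alone, and the list did not pass (median -0.23, adjusted p = 0.383). brat, a growth inhibitor in neuroblast daughters, fell (-0.96 ± 0.22).

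Of the early temporal list, 3 rose and 3 fell of 7 tested, also adjusted over the list alone, and the list did not pass (median 0.36, mean -0.80, test direction up, adjusted p = 0.899). chinmo rose to 589 ± 42.6 CPM (1.06 ± 0.17) and Imp to 791 ± 379 CPM (1.04 ± 0.33, adjusted p = 0.0212), while mamo fell (-5.87 ± 0.57). The adjusted p of Imp was 0.0782 without primary replicate 1, 0.0655 without primary replicate 2 and 0.120 without T3 replicate 2. Of the late temporal list, 2 rose and 6 fell of 12 tested, also adjusted over the list alone, and the list did not pass (median -0.76, adjusted p = 0.383). Syp fell to 996 ± 336 CPM (-1.24 ± 0.40, adjusted p = 0.0239) and Eip93F to 37.6 ± 5.88 CPM (-1.31 ± 0.40, adjusted p = 0.0170). For Syp the adjusted p was 0.122 without primary replicate 1, 0.0623 without primary replicate 2 and 0.0926 without T3 replicate 1. For Eip93F it was 0.124 without primary replicate 1, with a log2 fold change of -0.71, and 0.0618 without T3 replicate 1. Eip75B, an ecdysone-induced receptor gene, fell (-1.46 ± 0.27) and EcR rose (0.91 ± 0.16).

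Of the neuronal list, 2 rose and 20 fell of 25 tested (2 and 21 adjusted over the list alone), with a median of -3.82 (camera, adjusted p = 1.23e-08, and adjusted p = 0.588 with an estimated correlation). elav fell to 118 ± 24.3 CPM (-2.46 ± 0.24), and the GABA receptor gene Rdl fell too (-7.73 ± 0.44). cac and unc-13 rose here as well. Of the glial list, 1 rose and 4 fell of 10 tested, also adjusted over the list alone, and the list did not pass (median -0.64, adjusted p = 0.247). gcm, the switch gene for glial fate, fell (-2.44 ± 0.51), and repo was at 10.2 ± 5.44 CPM in primary and 6.03 ± 3.27 CPM in T3 and was not called. Of the Hox list, 0 rose and 6 fell of 6 tested, also adjusted over the list alone (camera, adjusted p = 4.36e-05, and adjusted p = 0.220 with an estimated correlation). Antp (3R, 6896253 to 6999228) had 2268 counts in primary and 1 in T3, a 2054-fold difference (counting interval 368 to 81159), and abd-A had 593 and 1 (537-fold, 96.0 to 21246). The log2 fold change of Antp was -10.54 ± 0.51, and it was -12.44 without T3 replicate 4 and -9.93 without T3 replicate 1. That of abd-A was -8.56 ± 0.89, and it was -7.67 without primary replicate 1 and -10.42 without T3 replicate 1. The Hox median was -7.30, and -6.80 with the members at 0 counts in T3 set to their bound. Of the optic lobe list, 0 rose and 7 fell of 14 tested (0 and 8 adjusted over the list alone), with a median of -0.87 (camera, adjusted p = 0.0169, and adjusted p = 0.611 with an estimated correlation). Vsx1 fell (-4.84 ± 0.43), as did ap (-3.02 ± 0.35).

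Of the antimicrobial list, 14 rose and 0 fell of 16 tested, also adjusted over the list alone, with a median of 4.38 (camera, adjusted p = 1.56e-04, and adjusted p = 0.611 with an estimated correlation). DptA had 451 counts in T3 and 0 in primary, at least 166-fold higher, and the antifungal peptide gene Drs rose from 0.370 ± 0.160 to 6.53 ± 4.72 CPM (4.07 ± 0.83). The fitted log2 fold change of DptA was 10.49 ± 2.04, and 9.35 without T3 replicate 2, sizes that are not exact with 0 counts in primary. Of the hemocyte list, 7 rose and 1 fell of 11 tested, also adjusted over the list alone, with a median of 1.91 (camera, adjusted p = 0.0329, and adjusted p = 0.738 with an estimated correlation). The list's adjusted p was 0.0512 without primary replicate 2 and 0.0508 without T0 replicate 3. The member that fell was the peroxidasin gene Pxn. Of the basement membrane list, 6 rose and 0 fell of 9 tested, also adjusted over the list alone, with a median of 1.65 (camera, adjusted p = 0.0493, and adjusted p = 0.778 with an estimated correlation). vkg, a collagen gene, rose to 19.7 ± 3.03 CPM (2.23 ± 0.54). The list's adjusted p was 0.105 without primary replicate 2 and 0.0599 without T3 replicate 1. Of the fat body list, 7 rose and 1 fell of 11 tested, also adjusted over the list alone, and the list did not pass (median 1.51, adjusted p = 0.102). It passed without T3 replicate 1 (0.0274). The lipase gene bmm rose (1.53 ± 0.16). Of the DNA damage response list, 13 rose and 1 fell of 16 tested, also adjusted over the list alone, with a median of 0.77 (camera, adjusted p = 3.67e-04, and adjusted p = 0.0901 with an estimated correlation). rad50 (1.61 ± 0.15) and Ku80 (1.66 ± 0.20), a gene of DNA end joining, were among them, and the member that fell was the checkpoint kinase gene grp.

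Of the oxidative phosphorylation list, 0 rose and 19 fell of 26 tested, also adjusted over the list alone, with a median of -0.55 (camera, adjusted p = 9.26e-04, and adjusted p = 0.778 with an estimated correlation). COX7A (-1.01 ± 0.17) and the citrate synthase gene kdn (-0.88 ± 0.14) fell. Of the growth list, 1 rose and 7 fell of 16 tested, also adjusted over the list alone, and the list did not pass (median -0.33, adjusted p = 0.0884). Myc rose (0.94 ± 0.22) and nop5 fell (-0.91 ± 0.17). Of the cell cycle list, 0 rose and 9 fell of 25 tested (0 and 5 adjusted over the list alone), and the list did not pass (median -0.29, adjusted p = 0.136). It passed without primary replicate 4 (0.0392). Of the glycolysis list, 1 rose and 3 fell of 14 tested, also adjusted over the list alone, and the list did not pass (median -0.30, adjusted p = 0.416). Ldh was at 134 ± 39.0 CPM in primary and 52.1 ± 50.9 CPM in T3 and was not called (adjusted p = 0.0801), but passed without T3 replicate 1 (log2 fold change -2.52, adjusted p = 0.00301). It also passed by limma-voom (-1.86, adjusted p = 0.0237) and with the replicate number as a block (-1.77, adjusted p = 0.00385). Of the heat shock list, 3 rose and 11 fell of 17 tested, also adjusted over the list alone, and the list did not pass (median -1.78, adjusted p = 0.0524). It passed without primary replicate 4 (0.0160), T0 replicate 2 (0.0169), T0 replicate 4 (0.0307), T3 replicate 2 (0.0481) or T3 replicate 1 (0.0487). Hr38 (-2.95 ± 0.40) and Hsp27 (-1.78 ± 0.29) fell, and handling again differed between the groups. Of the receptor tyrosine kinase list, 8 rose and 4 fell of 14 tested (8 and 5 adjusted over the list alone), and the list did not pass (median 0.71, adjusted p = 0.415). vn rose (2.73 ± 0.36), as did aos (1.82 ± 0.28). Of the JNK list, 4 rose and 2 fell of 11 tested, also adjusted over the list alone, and the list did not pass (median 0.50, adjusted p = 0.712). Ets21C, a transcription factor gene, rose (1.20 ± 0.24), and Mmp1 was at 5.84 ± 1.71 CPM and was not called. Of the JAK/STAT list, 3 rose and 1 fell of 9 tested (3 and 2 adjusted over the list alone), and the list did not pass (median 0.10, adjusted p = 0.712).

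In the muscle list 2 rose and 1 fell of 7 tested, also adjusted over the list alone (median -0.17, test direction up, adjusted p = 0.899). In the ovary and germline list 4 rose and 1 fell of 12 tested, also adjusted over the list alone (median 0.64, adjusted p = 0.557). In the trachea list 2 rose and 2 fell of 6 tested, also adjusted over the list alone (median 1.33, mean -0.07, test direction up, adjusted p = 0.899). In the sex list 1 rose and 0 fell of 6 tested, also adjusted over the list alone (median 0.09, adjusted p = 0.712). These 4 lists did not pass, and neither of the 2 gut genes tested was called. Among the largest decreases at a mean of at least 5 CPM were oc (at least 499-fold lower) and Dr (at least 274-fold lower), transcription factor genes with 0 counts in T3. Among the 10 largest increases were lin-28 and CG16857, CG7953, CG2003, CG14439 and CG16826, as the deposited table names them (CG16857 is bdl in the annotation). CG16826 had 206 counts in T3 and 0 in primary, at least 75.8-fold higher, so the size of its fitted log2 fold changes is not exact. Its adjusted p was 0.0869, 0.0779 and 0.0706 without primary replicates 1, 2 and 4. Without T3 replicate 2 it was not called (fitted log2 fold change 3.10, adjusted p = 0.361, against 9.49 with all libraries). By limma-voom CG16826 was not called (3.66, adjusted p = 0.241).

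The comparison of T3 with T0 asks whether tumours changed further between the first and the fourth transplantation. By the edgeR quasi-likelihood test, 0 of 9082 genes passed, with a smallest adjusted p of 0.330 and 746 genes at an unadjusted p under 0.05. chinmo was at 555 ± 116 CPM in T0 and 589 ± 42.6 CPM in T3 (log2 fold change 0.08 ± 0.17), and pros at 118 ± 26.1 and 107 ± 11.3 CPM (-0.15 ± 0.23). Hml was at 29.1 ± 16.3 and 17.7 ± 5.41 CPM (-0.71 ± 0.42).

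The count depended on the tool. DESeq2 called 13 genes (2 higher in T3, D and mid), and limma-voom called 0. The edgeR likelihood ratio test called 22 genes (5 higher, Brd, CG43109, D, H15 and mid). The quasi-likelihood test without the low-count filter called 96 genes (28 higher), 84 of them among genes that the filter keeps. With the filter it called 5 genes without T3 replicate 2 (CG16826, CG1678, Ag5r, CG45080 and Cyp4g1, all lower). The authors' table calls 26 genes (21 lower and 5 higher), 25 of which the test without the filter called too. By the authors' values, the eye and brain transcription factor genes toy (log2 fold change -2.30, adjusted p = 3.83e-06) and Vsx1 (-2.50, adjusted p = 5.11e-05) were lower in T3. So were the cuticle lipid gene Cyp4g1 (-2.39, adjusted p = 2.89e-05) and apolpp (Rfabg in the deposited table, -1.81, adjusted p = 0.0252). The transcription factor gene D (1.25, adjusted p = 0.0215) and the peptide gene Drs (2.94, adjusted p = 0.0474) were higher. Here these 6 genes had unadjusted p of 2.0e-04, 8.05e-05, 9.6e-05, 0.00128, 0.00156 and 0.00221 in that order of naming, and adjusted p of 0.330 to 0.591. The genes of this paragraph were chosen after their values were seen. The groups lay apart for 15.1% of genes, where chance gives 10%.

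As lists, 5 of 27 tested passed against T0 with the preset correlation, though 0 of their members passed over all genes. The antimicrobial list was higher in T3 (median 1.28, camera, adjusted p = 0.00165, and adjusted p = 0.706 with an estimated correlation), with 1 member higher adjusted over the list alone. Drs was at 0.860 ± 0.731 CPM in T0 and 6.53 ± 4.72 CPM in T3. The growth and ribosome biogenesis list was higher (median 0.15, adjusted p = 0.00849, and adjusted p = 0.706 with an estimated correlation), with 0 members adjusted over the list alone. Its adjusted p was 0.226 without T0 replicate 2 and 0.0572 without T3 replicate 2. The neuronal list was lower (median -0.36, adjusted p = 0.00385, and adjusted p = 0.709 with an estimated correlation), with 0 adjusted over the list alone. Its adjusted p was 0.122 without T0 replicate 4 and 0.0893 without T3 replicate 2. elav was at 168 ± 31.0 and 118 ± 24.3 CPM. The JAK/STAT list was lower (median -0.37, adjusted p = 0.0207, and adjusted p = 0.706 with an estimated correlation), with 0 adjusted over the list alone. Its adjusted p was 0.0956 without T0 replicate 3 and 0.0736 without T3 replicate 1. The hemocyte list was lower (median -0.89, adjusted p = 0.0174, and adjusted p = 0.706 with an estimated correlation), with 0 adjusted over the list alone. Its adjusted p was 0.262 without T0 replicate 2, 0.136 without T0 replicate 3 and 0.0850 without T3 replicate 4.

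The other 22 lists tested did not pass against T0. Of these, the basement membrane list (median -1.15, adjusted p = 0.0861) had 5 members lower in T3 adjusted over the list alone, Col4a1, vkg, Ndg, SPARC and Ppn. vkg was at 46.9 ± 40.1 CPM in T0 and 19.7 ± 3.03 CPM in T3. Without T0 replicate 2, the log2 fold change of vkg in T0 against primary was 2.57 against 3.48 with it. That of Col4a1 was 2.46 against 3.40, so the higher T0 levels rest in part on that library. The list passed without T0 replicate 3 (0.00424), T0 replicate 4 (9.77e-04) or T3 replicate 1 (0.0285). Its camera adjusted p reached 0.876 at the highest with 1 library left out. The fat body list (median -0.21, adjusted p = 0.0861) had 2 lower adjusted over the list alone, Yp3 (-1.98 ± 0.54) and apolpp (-1.82 ± 0.44), and passed without T0 replicate 4 (0.0485) or T3 replicate 2 (0.00305). The optic lobe list (median -0.34, adjusted p = 0.0986) had D higher (1.25 ± 0.31) and Vsx1 lower (-2.49 ± 0.43) adjusted over the list alone, and passed without T0 replicate 2 (0.0134) or T3 replicate 4 (0.0480). The early temporal list (median -0.72, adjusted p = 0.457) had 2 lower adjusted over the list alone, cas and svp, and the JNK list (median -0.32, adjusted p = 0.682) had 1, Mmp2. In the glial list (median -0.33, adjusted p = 0.467), repo was higher adjusted over the list alone (1.72 ± 0.49), and in the sex list (median -0.16, adjusted p = 0.125) lncRNA:roX1 was lower (-0.69). The sex list passed without T3 replicate 4 (0.0480). Both gut genes tested, Jon65Aiii and LManII, were lower adjusted over the list alone. The T0 level of Jon65Aiii rests in part on T0 replicate 2. Without that library its log2 fold change in T0 against primary was 3.98 against 5.70 with it. Counts adjusted over the list alone were 0 for the lists that follow. The asymmetric division list (median -0.17, adjusted p = 0.0861) passed without primary replicate 1 (0.0473), T0 replicate 2 (0.0134) or T3 replicate 4 (0.0315), the late temporal list (median -0.27, adjusted p = 0.0861) without primary replicate 1 (0.0333), and the oxidative phosphorylation list (median -0.01, adjusted p = 0.805) without T3 replicate 2 (0.0320).

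The remaining lists were those of the transgenes (median -0.06, adjusted p = 0.664), neuroblast identity (median -0.20, adjusted p = 0.696) and the Notch pathway (median -0.19, adjusted p = 0.217). The DNA damage response list (median 0.10, adjusted p = 0.125) and the receptor tyrosine kinase list (median -0.10, adjusted p = 0.521) did not pass either. The same held for the cell cycle list (median -0.0046, test direction up, adjusted p = 0.625), glycolysis (median -0.01, adjusted p = 0.953), heat shock (median -0.41, adjusted p = 0.953) and muscle (median -0.23, adjusted p = 0.296). Median and test differed in direction for the ovary list (median -0.18, test direction up, adjusted p = 0.886) and the trachea list (median -0.07, test direction up, adjusted p = 0.824), and median and mean did for glycolysis. The Hox list had a median of -1.31, or -0.40 with members at 0 counts at their bound (adjusted p = 0.367). Antp had 6 counts in T0 and 1 in T3, and Ubx 12 and 3. At these counts the difference in Antp was not detectable (ratio 5.99, counting interval 0.727 to 275). For Ubx the ratio was 3.99 (counting interval 1.08 to 22.0), and it was not called. dpn was at 253 ± 73.6 CPM in T0 and 243 ± 19.7 CPM in T3, and rad50 at 389.5 ± 60.1 and 367 ± 29.9 CPM. Without T3 replicate 4, 8 lists passed in all.

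Primary libraries serve both T0 and T3 comparisons. The genes called with the same direction in both were 3503, of which 1700 were higher and 1803 lower than in primary, and 0 genes were called in opposite directions. Independent lists of these sizes would share 470 and 507, and 20 simulations of unchanged groups against the shared primary libraries called 0 genes in both. The simulations hold no real effects, so they cannot show what shared controls add where effects are real. The 3 primary libraries cannot be split between the comparisons, so part of the excess of genes called in both may come from the shared controls. Another 641 genes were called only in T0 against primary and 781 only in T3, and the direct test of T3 against T0 called 0 of all genes by the quasi-likelihood test. Across genes, the correlation of the 2 sets of log2 fold changes was 0.955, against 0.498 in the simulations, and their covariance 2.62 against 0.0556.

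**Figure D4:**
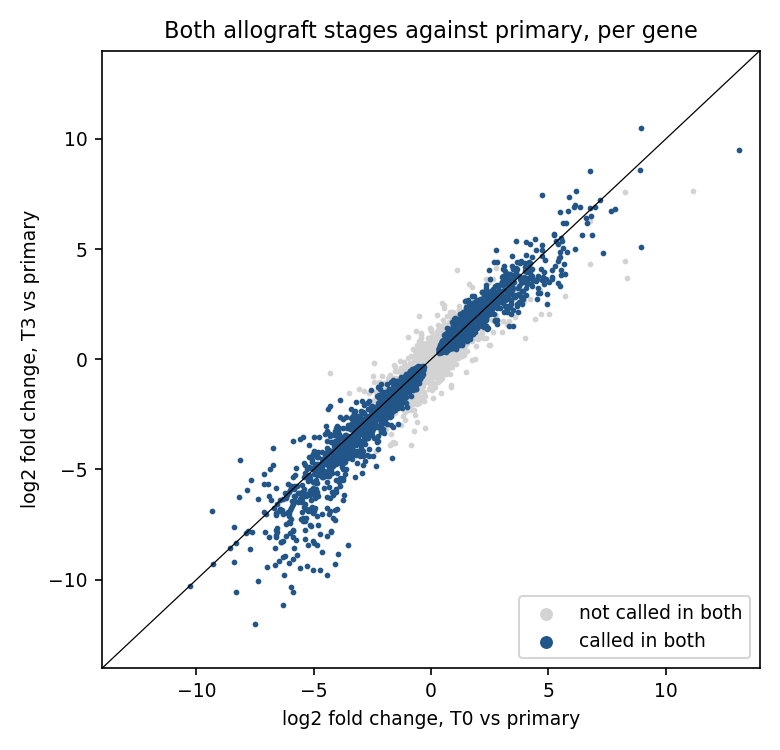
Log2 fold change of T3 against primary on the vertical axis and of T0 against primary on the horizontal axis, 1 point per gene tested. The correlation across genes is 0.955, and 0 genes called in both comparisons lie on opposite sides of 0.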

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

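The likelihood ratio test and the model with 1 surrogate variable were chosen only after the results were seen. The genes called in T0 against primary numbered 3799 (replicate block) to 4525 (1 surrogate variable), and those in T3 against primary 4249 (CPM filter) to 4679 (1 surrogate variable), except that a test against a 1.5-fold change called 1898 and 2006, fewer because it asks for more than a difference from 0. Leaving out 1 library gave 3562 to 4152 and 3492 to 4681 genes, and 2995 to 3327 shared genes. The shared genes numbered 3201 (replicate block) to 3667 (DESeq2). Between T3 and T0, where 0 genes were called, no filter called 96, DESeq2 13, the replicate block 5 (Vsx1, Cyp4g1, Rfabg, CG30463 and CG34370) and the likelihood ratio test 22, and leaving out 1 library 0 to 5. The other settings called 0 there, and the cause was not tested. For genes near 0 counts depth limits the size of a fold.

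With an estimated correlation 0 lists passed in each comparison. The adjusted p values in T0 against primary were then 0.163 (Notch, DNA damage), 0.213 (Hox), 0.519 (neuronal, fat body), 0.620 (growth, hemocytes, basement membrane, optic lobe) and 0.656 (oxidative phosphorylation, antimicrobial, heat shock). In T3 against primary they were 0.0901 (Notch, DNA damage), 0.220 (Hox), 0.588 (neuronal), 0.611 (antimicrobial, optic lobe), 0.738 (hemocytes) and 0.778 (oxidative phosphorylation, basement membrane). In T3 against T0 they were 0.709 (neuronal) and 0.706 (growth, JAK/STAT, antimicrobial, hemocytes). The estimate lets the genes of a list vary together. For the DNA damage list it was 0.0014, below the preset 0.01. Yet that list's unadjusted camera p in T0 against primary rose from 2.68e-04 to 0.00828. Members varying together thus cannot alone account for the loss of its call. With an estimated correlation, camera also takes its degrees of freedom from the few libraries and not from the genes. That raises p at a given statistic. How much each adds per list was not tested.

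The number 3 belongs to T0 replicate 3 alone, so the block fit in effect leaves that library out. The replicate block moved more lists past the threshold: cell cycle (0.0182) and ovary (0.0305) in T0 against primary, fat body (0.0439) and heat shock (0.00821) in T3 against primary. In T0 against primary, leaving out T0 replicate 3 without a block moved cell cycle too (0.0149). Ovary reached 0.168 at the lowest with any library left out. In T3 against T0, 10 lists passed with it, 3 of them among the 5 called without it. They included late temporal (0.0213), basement membrane (0.00342), and cell cycle, receptor tyrosine kinase and muscle (0.0317 each), while JAK/STAT (0.0629) and hemocytes (0.187) no longer passed. Oxidative phosphorylation (0.00640) and ovary (0.00677) turned direction with it and passed. Whether the replicate numbers pair the libraries cannot be told. Residuals of libraries with 1 number correlated across genes at -0.06 to 0.26. Between T0 and T3, those numbered 2 correlated at 0.200 and those numbered 4 at 0.256. T0 and T3 libraries of unlike number ranged from -0.445 to 0.33, the highest for T0 replicate 3 and T3 replicate 4. These pairs are too few to decide. On the 6 libraries of a comparison, heat shock passed in T3 against primary (0.0169), and 8 lists passed in T3 against T0, with Notch (0.0484), late temporal (0.0261) and asymmetric division (0.0397) among them. The cause was not tested.

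Leaving out 1 library moved some lists across the threshold. Their adjusted p values in T0 against primary ranged from 0.0107 to 0.359 for cell cycle, 0.00143 to 0.122 for heat shock and 0.0109 to 0.0716 for optic lobe. In T3 against primary they ranged from 0.0274 to 0.168 for fat body, 0.0196 to 0.105 for basement membrane, 0.0392 to 0.343 for cell cycle, 0.0160 to 0.115 for heat shock and 0.0126 to 0.0512 for hemocytes. In T3 against T0 they ranged from 0.00305 to 0.236 for fat body, 0.0134 to 0.423 for asymmetric division, 9.77e-04 to 0.876 for basement membrane, 8.71e-04 to 0.226 for growth, 3.50e-07 to 0.262 for hemocytes, 0.0131 to 0.0956 for JAK/STAT, 0.0333 to 0.423 for late temporal, 4.09e-05 to 0.122 for neuronal, 0.0134 to 0.388 for optic lobe, 0.0320 to 0.936 for oxidative phosphorylation and 0.0480 to 0.510 for sex. The number of lists passing ranged from 10 to 14, 7 to 11 and 4 to 8 in these comparisons. The cause was not tested beyond there being fewer libraries.

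Of the alternatives for list tests, 967 of 1052 kept direction and side of the threshold, 50 of them counted as kept although an uncalled list changed sign. Of those for named genes, 5542 of 5756 did, 27 of them with an uncalled change of sign, and no called gene reversed.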

Other observations

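The tests of blood cells, fat body, muscle, scaling, neuron number, the likelihood ratio and the surrogate variable were chosen only after the results were seen, and the counts of other splits were chosen before. Genes on the chromosome arms were compared as medians of log2 CPM against the primary mean, over genes with a mean of at least 10 CPM. The 68 genes of chromosome 4 had medians of 0.196, -0.213 and 0.191 in T0 replicates 2, 3 and 4, and of -0.351, -0.0733 and -0.0513 in T3 replicates 2, 4 and 1. The primary libraries had 0.148, -0.132 and 0.0035. The 1140 genes of the X had medians of 0.0541, 0.105 and 0.0640 in T0 and -0.0101, 0.0567 and -0.0308 in T3.

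The 6 libraries of a comparison allow 10 splits into 3 and 3, too few for a share under 0.05. For T0 against primary the real split, fitted on the 6 libraries, called 3809 genes, the highest other split called 0, and 1 split reached the real value. For T3 against primary the real split called 4282 genes, the highest other 0, and 1 split reached it. For T3 against T0 the real split called 0, so all 10 splits reached it, and the highest other called 69. That split set T0 replicate 2 with T3 replicates 2 and 1 against T0 replicates 3 and 4 with T3 replicate 4. The second principal component parts the libraries in the same way, but it comes from the same counts and is no independent support. Since this split was picked as the highest, a structure among these libraries other than the group stays open.

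Of the 11 hemocyte genes tested, 8 rose in T0 and 7 in T3 against primary, and of the 11 fat body genes 8 and 7, but the fat body list did not pass in T3 (adjusted p = 0.102), and no such call held for either list (adjusted p = 0.519 to adjusted p = 0.738 with an estimated correlation). Host muscle collected with the masses is argued against as the main source. The highest of 18 muscle genes reached a mean of 3.26 CPM in T0 or T3, without TMM scaling. That lies below Hml at 29.1 and 17.7 CPM with TMM scaling, and does not bear on other host tissues. Host blood cells could contribute, but the test cannot decide. Hemocyte genes rose and fell together over the 6 libraries (mean correlation 0.569, 99.98th percentile of 10000 random lists). So did the 7 muscle genes tested, also of a host tissue (0.489, 98.03rd percentile). But neuronal and oxidative phosphorylation genes, not tied to host cells, rose and fell together too (0.399 and 0.679). Fat body genes did so less (0.0736, 81.6th percentile), which leaves host fat body open. Expression of these genes by the tumour cells was not tested, and sorting removed unlabelled cells from the primary group alone.

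Of 25 neuronal genes, 20 fell and 2 rose in T0 and as many in T3 against primary (adjusted p = 0.519 and adjusted p = 0.588 for the list with an estimated correlation). Library scaling is argued against, because 1 factor per library moves all genes alike, while the neuronal median minus that of all genes was -3.44 in T0 against primary. With RLE factors the neuronal median was -3.45. A smaller share of neurons beside the stem-like cells may account for the pattern, but neuroblast identity genes went both ways, with a median of -0.0421, which decides nothing. Lower expression within cells and a smaller share of neurons cannot be told apart here, since sorting, host and growth time change with the group.

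The authors' table calls 26 genes between T3 and T0, where the quasi-likelihood test called 0. The choice of test or of filter may account for most of the difference, and they cannot be told apart here. A likelihood ratio test called 20 of the 26. The quasi-likelihood test without the low-count filter called 25 of them, but the authors' table holds tests of 8958 genes, fewer than the 9082 tested here. An unlabelled difference among the libraries stays open, since models with and without 1 surrogate variable both called 0 genes, which decides nothing. A biological difference between T0 and T3 stays open and untested beyond these counts.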
